A study of Mus musculus with 15 samples.

How the data were processed

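Spatial transcriptomes of mouse pancreas were compared in 15 formalin-fixed sections, 3 in each of 5 groups. Per the labels, 9 sections held orthotopic tumours of the pancreatic line PKC-HY19636 (HY): 3 from mice whose treatment is given as vehicle and whose titles read C57 and isotype/vehicle, 3 from mice given the KRAS G12D inhibitor MRTX1133 and called sensitive, both after 1 week, and 3 called resistant after 5 weeks of MRTX1133. The other 6 came from KC mice, which carry an oncogenic Kras allele switched on in the pancreas by Pdx1-Cre: 3 on vehicle and 3 on MRTX1133 for 18 weeks. The labels do not say that replicates are separate animals, so every p-value measures spread between these sections. Only the titles of HY controls name an isotype, and whether one was given is not stated, so its effect was not tested. The labels give vehicle sections of the HY model at 1 week only, so resistance and length of treatment changed together.

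Per the labels, libraries were made with the probe-based Visium CytAssist chemistry for fixed tissue, and the submitters' processing notes name Space Ranger 2.0.1 and mm10. The authors deposited 1 matrix of UMI counts per section (19465 genes by spots). Checks on the files found whole, non-negative counts, the same genes in the same order in every section, and no duplicated library. In 7 sections all 4992 spots of the capture area were flagged as tissue, so any spots off the tissue were not removed from them. The files do not join spots to positions, so spots were described by their transcripts alone. Cxcl2, Krt18 and other list members outside the matrix were not analysed here.

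Spots with at least 100 UMIs were summed per section, because spots of 1 section are not replicates. A second sum, called acinar-low spots, took spots in which a fixed list of acinar digestive enzymes held under 10% of UMIs, and left those enzymes out of the tests. A section entered it with at least 50 such spots and 50000 UMIs, which left out HY sensitive section 1 (44 spots) and KC MRTX1133 section 2 (44734 UMIs). Deposited depth ran from 24777948 to 118297136 UMIs in HY sections and from 2472781 to 21871012 in KC sections, with median UMIs per spot from 9267 to 25013.5 and from 368 to 4622. For the better expressed genes that the simulations below changed, recovery differed between the models. Whether depth or the spread between sections brought this about was not tested.

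Counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment at a false discovery rate of 0.05). The 9 HY sections shared 1 fit, the 6 KC sections another, and all 15 entered the test of the difference between the models' effects. CPM are TMM-scaled unless said otherwise and given as mean and SD over sections. The standard error (SE) beside a log2 fold change is its size over the square root of the test's F statistic. It therefore follows the test and is not a separate estimate of spread. Unless another tool is named, adjusted p-values of genes come from edgeR. Gene lists, 36 fixed before the data were examined, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry, for lists with at least 4 members tested. R was 4.3.3, DESeq2 1.42.0, and summing and plotting used Python with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

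The fits were tested on simulated data with the real library sizes and dispersions. Each gene had the same mean level in all sections of a fit, its average over them. Simulated levels of a gene were thus equal in HY and KC for the difference between models, unlike those of real genes such as Adm. Changes were planted only in genes over a set mean CPM, so recovery in genes under it was not measured. Of 100 genes changed by a log2 of 3, edgeR recovered 95 in HY sensitive against vehicle, 93 in HY resistant against vehicle, 93 in HY resistant against sensitive, 79 in KC and 54 for the difference between models, in whole sections. Of 100 genes changed by a log2 of 1 it recovered 2, 3, 4, 1 and 0 in the same order. In acinar-low spots it recovered all 100 at a log2 of 3 and 28, 35 and 24 of 100 at a log2 of 1 in the 3 HY comparisons, against 54 of 100 and 1 of 99 in KC. False calls were between 5.8% and 8.9% of calls, except 13.8% in KC acinar-low spots.

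Genes were named by a rule fixed before the data were examined: among genes past the threshold, with CPM not overlapping between the groups and a mean of at least 10 CPM in the higher group, the 6 with the largest rise and the 6 with the largest fall, leaving out the acinar enzymes and Xist, Tsix and Y-linked genes. Added to these were up to 4 called members of each list described, or 2 with the lowest p where none was called, and Cdk8, Kras, Dusp6 and Mki67 in every comparison. The condition on overlap was not applied to the difference between models, where it has no meaning. The report names part of what the rule allows, kept by hand after the results were seen. Counts of named or followed genes that held under alternatives cover this part alone. Alternatives covered scaling, filters, spot limits, other tools, a replicate block, thinned counts, the sections in the fit and each section left out. The presence of Y-linked transcripts was added as a covariate after the data were seen. The labels give groups the same replicate numbers without saying what they stand for, so the deviations of same-numbered sections from their group means were correlated. In resistant and vehicle sections all 3 pairs lay over 0.1, at 0.363 to 0.613 in whole sections and 0.328 to 0.608 in acinar-low spots, so values with a replicate block are given for that comparison. This rests on the correlations alone. In the other comparisons at least 1 pair lay under 0.1.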

Results

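Exocrine pancreas made up very different parts of the sections. Digestive enzymes of acinar cells took 6.92% of UMIs on average (SD 7.79, n = 3) in HY vehicle sections, 24.8% (SD 34.0) in HY sensitive sections and 0.012% (SD 0.014) in HY resistant sections. In KC sections they took 50.6% (SD 18.0) on vehicle and 59.2% (SD 8.30) on MRTX1133. HY sensitive section 1 stood apart from its group, with enzymes at 63.5% of its UMIs. It held 11.4 CPM of Kras and 2.22 CPM of the cell cycle inhibitor gene Cdkn2a, against at least 381 and 490 CPM in the other 8 HY sections, all before TMM scaling. Cdkn2a was chosen after its values were seen. The 4 comparisons within a model were therefore made on whole sections and on acinar-low spots, where that section did not enter. The difference between the models was tested on whole sections alone, with that section among them. Transcripts of Y-linked genes were absent from HY vehicle sections 1 and 2, KC vehicle section 1 and KC MRTX1133 section 3 and present in the others, so sex differed within and between groups.

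**Figure D1:**
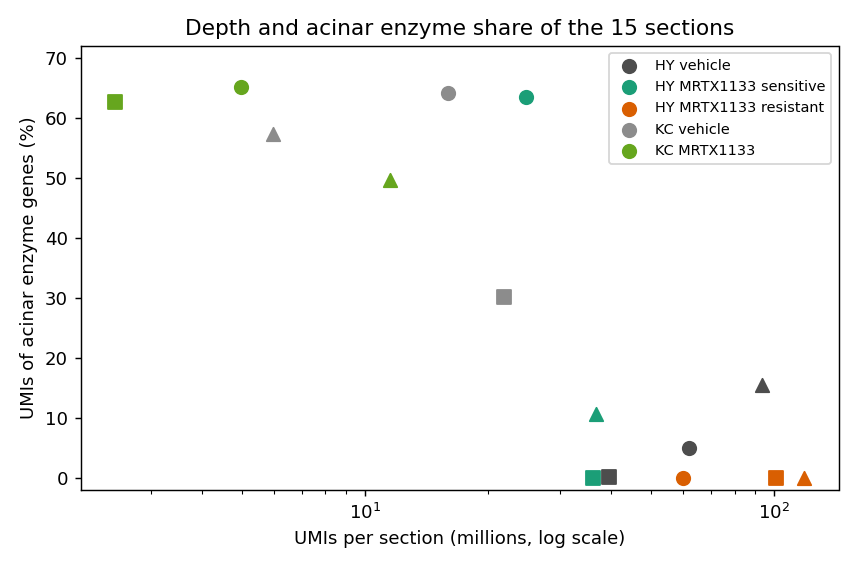
Each point is 1 of the 15 sections, placed by its UMIs (log axis) and by the percent of UMIs from acinar enzyme genes, with colour for group and marker shape for replicate number. HY resistant sections lie at or under 0.028%, and KC sections lie between 30.1% and 65.1%.

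In whole HY sections, genes of hypoxia and glycolysis, of the MAP kinase ERK's output and of the cell cycle were lower in sensitive sections after 1 week of MRTX1133 than in vehicle sections. As lists they were called at the preset correlation and none held with an estimated one (each adjusted p = 0.829 with an estimated correlation). The means include sensitive section 1, which held few tumour transcripts, and 5177 genes passed without it against 4061 with it. All 12 tested members of the hypoxia and glycolysis list fell (12 also when adjusted over the list alone). Among them were Adm, which encodes the vasodilator adrenomedullin (from a mean of 259 CPM, SD 60.1, to 9.14, SD 1.70; log2 fold change -4.82, SE 0.40, adjusted p = 0.00136). The glycolytic enzyme gene Pgk1 (-3.38, SE 0.47, adjusted p = 0.00491) and the mitophagy gene Bnip3 (-2.78, SE 0.35, adjusted p = 0.00404) belonged to them too. Of 17 genes of ERK output, 9 fell and none rose (14 fell when adjusted over the list alone). The phosphatase gene Dusp6, an ERK feedback inhibitor, went from 507 CPM (SD 57.8) to 94.6 (SD 64.0), a log2 fold change of -2.42 (SE 0.62, adjusted p = 0.0249). Dusp5 fell by 4.31, the AP-1 gene Fosl1 by 3.36 and the feedback gene Spry4 by 2.15. Of 20 cell cycle genes, 12 fell and none rose (17 adjusted over the list alone). The proliferation marker Mki67 stood at -1.77 (SE 0.37, adjusted p = 0.0134), the mitotic cyclin gene Ccnb2 at -2.35 and the checkpoint kinase gene Bub1 at -2.60. Gastric-type genes fell in 8 of 14 members (8 adjusted over the list alone), among them the mucosal peptide gene Tff1 (-4.20, SE 0.98) and the secretory pathway gene Agr2 (-4.20, SE 0.81; -2.55 without vehicle section 2, adjusted p = 0.0255). Ductal epithelial genes fell in 3 of 12 (6 adjusted over the list alone), among them the tight junction gene Cldn4 (-2.89, SE 0.42, adjusted p = 0.00522).

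Wide falls in whole sensitive sections came in the transcriptional co-activator gene Cited1 (-5.70, SE 0.58), the mucosal peptide gene Tff3 (-5.08, SE 1.34) and Adm. Tff3 stood at -2.63 without vehicle section 2 (edgeR adjusted p = 0.119) and was not called without sensitive section 2 either (-5.14, edgeR adjusted p = 0.056). The plasminogen activator inhibitor gene Serpine1 (-4.71, SE 1.16), the gastric gene Gkn2 (-4.53, SE 0.73) and the cartilage proteoglycan gene Acan (-4.35, SE 0.73) followed, with edgeR adjusted p of these 6 falls between 0.00136 and 0.0268. Wide rises came in the drug-metabolising gene Cyp2e1 (6.11, SE 1.53), the sodium pump subunit gene Fxyd2 (5.66, SE 1.46) and the carbonic anhydrase gene Car3 (5.28, SE 1.24). Next came the gluconeogenesis gene Pck1 (4.95, SE 1.31), Cyp2j5 (4.39, SE 1.30) and the organic anion transporter gene Slc22a8 (4.36, SE 1.30). Fxyd2, Slc22a8 and Cyp2j5, which kidney tubules express, came almost wholly from section 1: 186, 29.3 and 38.2 CPM there against at most 3.00, 0.652 and 1.10 in the other sensitive sections. Without section 1 they stood at 1.26 (edgeR adjusted p = 0.0246), 0.47 (edgeR adjusted p = 0.375) and 0.82 (edgeR adjusted p = 0.277), and Pck1 at 2.81 (edgeR adjusted p = 0.0361). Of 9 adipocyte genes 4 rose (7 adjusted over the list alone), with the lipid droplet gene Plin1 at 4.37 (SE 0.99, adjusted p = 0.0164). Kras (-1.39, SE 0.77, edgeR adjusted p = 0.181) and the Mediator kinase gene Cdk8 (-0.71, SE 0.46, edgeR adjusted p = 0.235) did not pass the test.

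By edgeR, 4061 of 19233 genes passed in this comparison, 1485 higher and 2576 lower, and 47.9% of all tested genes did not overlap between the groups, where chance gives 10%. The count was 527 without HY vehicle section 1, 749 without HY vehicle section 2, 1688 in a fit of these 6 sections alone and 12 with the presence of Y-linked transcripts as a covariate. Of 30 called genes followed, 13 stayed called with any 1 section left out, Adm, Cited1, Dusp5 and Ccnb2 among them. Dusp6 lost its call without vehicle section 1 (-2.42, edgeR adjusted p = 0.0788) or 2 (-2.33, edgeR adjusted p = 0.078), and Mki67 without vehicle section 1 (-1.75, edgeR adjusted p = 0.057). Dusp6 also lost it with a replicate block (edgeR adjusted p = 0.0525), in the fit of 6 sections (edgeR adjusted p = 0.0631) and with the Y-linked covariate (edgeR adjusted p = 0.277), and Mki67 with that covariate (edgeR adjusted p = 0.173). By camera, 10 of 36 lists were called at the preset correlation, 3 higher and 7 lower. None was called with an estimated correlation (lowest adjusted p = 0.829 with an estimated correlation). That correlation had a median of 0.53 over the lists, against the preset 0.01. Fry called the hypoxia list alone (adjusted p = 0.00595). Of the 10 splits of these sections, 9 gave as many lists at the preset correlation. At the preset correlation hypoxia and glycolysis (adjusted p = 3.49e-09), cell cycle (3.08e-07), ERK output (1.53e-06), gastric-type, ductal, YAP targets (F3, the tissue factor gene, at -4.30) and myofibroblast genes (the matrix gene Postn at -2.02) were lower. Adipocyte, T cell and B and plasma cell genes were higher. In the T cell list none of 14 members passed singly, with Cd3d at 1.16 (SE 0.42, edgeR adjusted p = 0.0692). In the B and plasma cell list 2 of 12 rose, among them the receptor gene Tnfrsf17 (1.54, SE 0.37, edgeR adjusted p = 0.0206).

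In acinar-low spots, which compared sensitive sections 2 and 3 with the 3 vehicle sections, stromal, vascular and immune genes were higher while the epithelial programmes were lower. These list calls were made at the preset correlation, and none held with an estimated one (lowest adjusted p = 0.646 with an estimated correlation). CPM are shares of all transcripts in the spots. A smaller share of tumour cells could thus raise stromal, vascular and immune genes without a change in the cells that express them. This was not set apart from the rises given here and below. All 12 hypoxia genes fell again, with the glucose transporter gene Slc2a1 at -3.25 (SE 0.38, adjusted p = 0.000186). ERK output fell in 15 of 17 members (15 adjusted over the list alone), with Dusp6 at -1.91 (SE 0.38, adjusted p = 0.0026), Dusp5 at -3.79 (SE 0.38) and Fosl1 at -2.85 (SE 0.38). Cell cycle genes fell in 15 of 20 (15 adjusted over the list alone), with Mki67 at -1.49 (SE 0.32, adjusted p = 0.00407) and Ccnb2 at -2.02 (SE 0.24). Gastric-type genes fell in 11 of 14 (12 adjusted over the list alone; Tff1 -3.61, Vsig1 -2.57). Ductal genes fell in 6 of 12 (6 adjusted over the list alone; Cldn4 -2.56, the keratin genes Krt7 -2.38 and Krt19 -1.75). All 6 genes of the Reg family of secreted lectins, which injured acinar cells make, fell too (6 adjusted over the list alone). Reg3b went from 620 CPM (SD 370) to 7.05 (SD 2.31), a log2 fold change of -6.46 (SE 0.68, edgeR adjusted p = 0.000126). Reg3g fell by 5.50, Reg2 by 5.30 and Reg3a by 5.18. Members of this family are close in sequence, and whether their probes tell each of them apart was not tested. Acinar-low spots could still hold enzyme transcripts at under 10% of UMIs, so leftover acinar tissue was not set apart from these falls.

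On the rising side of the acinar-low comparison, macrophage genes rose in 8 of 14 members and fell in 1 (11 and 1 adjusted over the list alone). They included the lipid receptor gene Trem2 (2.44, SE 0.30), Ms4a7 (2.82, SE 0.28) and the macrophage marker gene Adgre1 (1.83, SE 0.28). Myeloid chemokine and cytokine genes rose in 8 of 13 and fell in 1 (the same counts adjusted over the list alone). The inflammatory cytokine gene Il1b went from 5.91 CPM (SD 3.24) to 53.0 (SD 16.02), a log2 fold change of 3.17 (SE 0.39, edgeR adjusted p = 0.000223). Ccl7 rose by 2.47 and Cxcl1 by 2.36. Endothelial genes rose in 8 of 12 (10 rose and 1 fell adjusted over the list alone), with the receptor genes Kdr at 2.05 and Tek at 2.33. Fibroblast genes rose in 7 of 14 (8 adjusted over the list alone; the matrix gene Dcn 2.57, the receptor gene Pdgfrb 1.56). Inflammatory fibroblast genes rose in 7 of 11, with 1 lower (Pi16 2.82, Clec3b 3.27). T cell genes rose in 4 of 14 (Cd5 1.99, the kinase gene Lck 1.17). Dendritic cell genes rose in 5 of 12 (7 adjusted over the list alone; the transcription factor gene Zbtb46 2.35, Cd209a 2.25). Interferon response genes rose in 7 of 14, with 1 lower (Stat1 1.56, Cxcl10 1.88; Oasl1 -2.58). Among apoptosis genes, a list that was not called (adjusted p = 0.126), the death receptor gene Fas rose by 1.68 (SE 0.29) and the executioner caspase gene Casp3 fell by 2.09 (SE 0.34).

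Wide single rises in these spots came in Car3 (5.32, SE 1.12), Cyp2e1 (5.16, SE 1.25) and the adipocyte protease gene Cfd (4.79, SE 1.45). After them came the growth factor gene Gdf10 (4.70, SE 0.64), Itgbl1 (4.09, SE 0.28) and the collagen gene Col6a5 (4.01, SE 0.70), with edgeR adjusted p between 2.89e-05 and 0.0247 for the 6. Adipocyte genes rose in 5 of 9 (9 adjusted over the list alone; Plin1 3.99). Cdk8 fell from 10.8 CPM (SD 4.50) to 4.65 (SD 0.141), a log2 fold change of -1.21 (SE 0.42, edgeR adjusted p = 0.0447). That call was lost without vehicle section 1 (-1.003, edgeR adjusted p = 0.152) or 2 (-1.05, edgeR adjusted p = 0.106) or sensitive section 2 (-1.18, edgeR adjusted p = 0.221) or 3 (-1.25, edgeR adjusted p = 0.166), and with the Y-linked covariate (-0.27, edgeR adjusted p = 0.796). It was lost as well with a replicate block (-0.89, edgeR adjusted p = 0.0511), with all deposited spots (edgeR adjusted p = 0.135) and at the 20% acinar limit (edgeR adjusted p = 0.098). None of the 7 genes of its Mediator kinase list was called when adjusted over the list alone. Kras did not pass (-0.80, SE 0.31, edgeR adjusted p = 0.0705). Cited1 and Adm fell here by 5.56 and 4.74. By edgeR 5624 of 19213 genes passed, 2460 higher and 3164 lower, and 59.6% of tested genes did not overlap, where chance gives 20% for 2 against 3 sections. The count was 1933 without sensitive section 2, 2626 without sensitive section 3, and 1701 with the Y-linked covariate. Fits without sensitive section 2 or 3 leave 1 section in that arm, which is assumed to vary like the other groups. Of 47 called genes followed, 44 stayed called in the fits that kept 2 or more sections per group, and 40 when those with a lone section are counted too. The others were Cdk8, Cd5, Lck, Cfd, Krt19, Dusp6 (-1.70 without sensitive section 2, edgeR adjusted p = 0.0507) and Mki67 (-1.32 without it, edgeR adjusted p = 0.0691). Camera called 15 of 35 lists, 9 higher and 6 lower, none with an estimated correlation (lowest adjusted p = 0.646 with an estimated correlation). Fry called 7 of them.

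**Figure D2:**
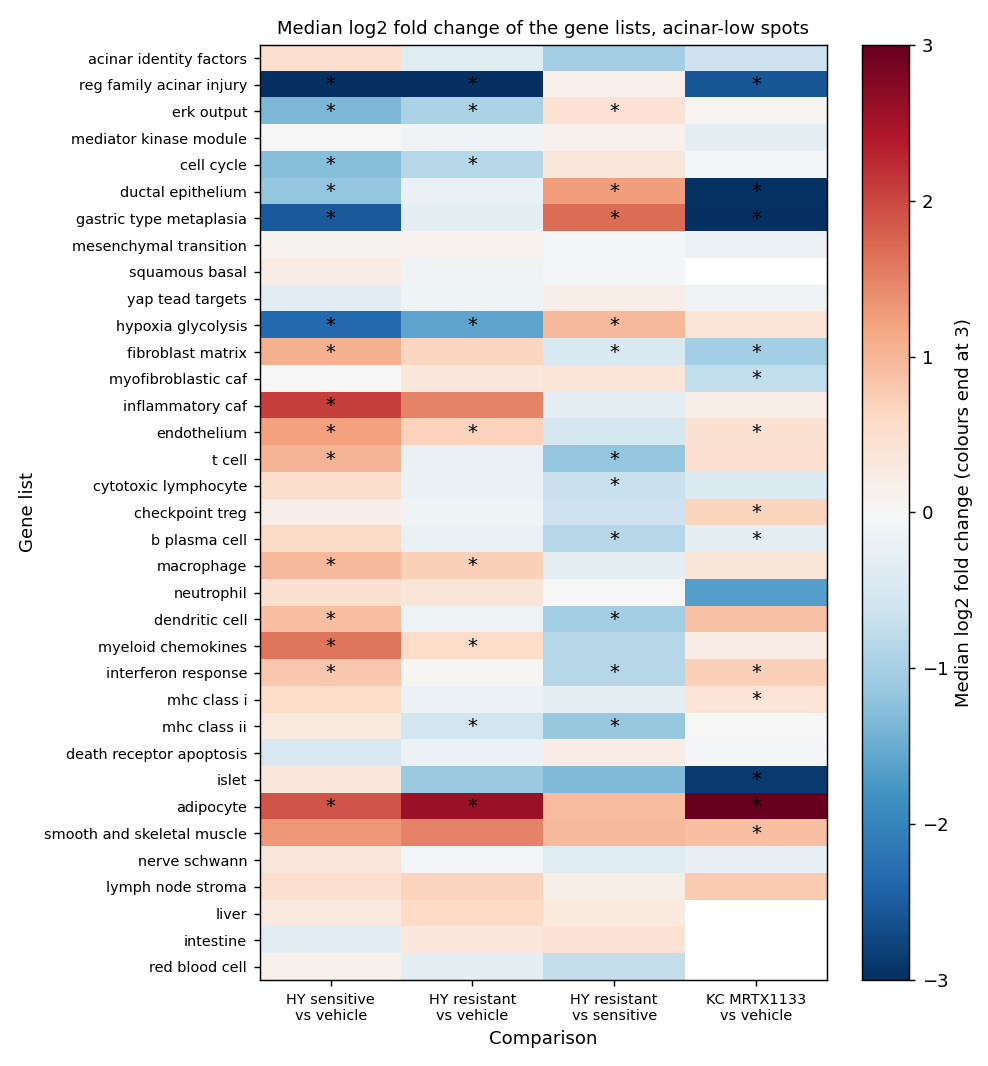
Median log2 fold change (colour, red higher and blue lower, ending at 3) of each fixed gene list in acinar-low spots, by list and comparison, with an asterisk where camera's adjusted p at the preset correlation was under 0.05. The hypoxia list stood at -2.34 in HY sensitive against vehicle sections, and no call held with an estimated correlation.

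Over whole sections, few genes passed between resistant HY sections after 5 weeks of MRTX1133 and vehicle sections in the fit of all 9 HY sections. That fit shared its spread with sensitive section 1. It called 28 genes, against 409 in a fit of the 6 sections compared. Higher were Cck, which encodes the peptide hormone cholecystokinin (from 1.47 CPM, SD 0.463, to 73.9, SD 7.96; log2 fold change 5.64, SE 0.33, edgeR adjusted p = 3.5e-05), and the potassium channel gene Kcnj12 (3.81, SE 0.57). So were Wfdc1 (3.77, SE 0.57), the intestinal crypt gene Olfm4 (3.23, SE 0.46), the mucus gene Fcgbp (3.19, SE 0.50) and the basal keratin gene Krt14 (3.16, SE 0.39). Lower were the immediate-early transcription factor gene Egr1 (from 207 CPM, SD 129, to 0.673, SD 0.420; -8.28, SE 1.15, edgeR adjusted p = 0.0301) and the transcription factor gene Nfatc1 (-5.52, SE 0.32, edgeR adjusted p = 3.5e-05). Lower too were Cyp2d22 (-3.72, SE 0.35), the kinase gene Stk38 (-3.43, SE 0.30), Frg1 (-2.79, SE 0.38) and Adm (-2.74, SE 0.36). Dusp6 (-1.78, SE 0.61, edgeR adjusted p = 0.443), Mki67 (-1.08, SE 0.36, edgeR adjusted p = 0.43), Kras (1.17, SE 0.76, edgeR adjusted p = 0.912) and Cdk8 (-0.23, SE 0.45, edgeR adjusted p = 0.998) did not pass.

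By edgeR 28 of 19233 genes passed, 9 higher and 19 lower, with 1407 at an unadjusted p under 0.05. DESeq2 called 301, and a fit of these 6 sections alone called 409. The count was between 5 and 15 with any 1 of these sections left out, 5 with the Y-linked covariate and 9 with a replicate block. Of the 12 called genes named, only Cck, Nfatc1, Cyp2d22 and Stk38 stayed called with any 1 section left out. Olfm4, Fcgbp and Frg1 lost their calls in all 6 of these fits and Egr1, Adm, Krt14, Kcnj12 and Wfdc1 in 5 of 6, and of these 8 the block kept Krt14 alone. Camera called 12 of 36 lists, 4 higher and 8 lower, and none with an estimated correlation (lowest adjusted p = 0.441 with an estimated correlation). The acinar enzyme list was lower at a median of -9.07 with no member past the test over all genes (21 of 25 adjusted over the list alone; Pnlip, the pancreatic lipase gene, -10.65, SE 2.97, edgeR adjusted p = 0.302).

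In acinar-low spots of resistant sections, hypoxia genes, ERK output and Reg genes lay below vehicle. These list calls were made at the preset correlation, and none held with an estimated one (lowest adjusted p = 0.588 with an estimated correlation). Hypoxia genes fell in 11 of 12 members (12 adjusted over the list alone), with Adm at -2.79 (SE 0.31, adjusted p = 0.000485), Slc2a1 at -2.06 (SE 0.30) and Ndrg1 at -1.96 (SE 0.26). ERK output fell in 7 of 17 (13 adjusted over the list alone), with Dusp6 at -1.81 (SE 0.32, adjusted p = 0.00757), Spry4 at -1.47 (SE 0.33) and the ETS factor gene Etv5 at -1.24 (SE 0.22). Egr1 is a member of this list and among the 7, and a lower yield of its probes in the resistant libraries stays open. The list was not tested without Egr1. Of 20 cell cycle genes, 4 fell (13 adjusted over the list alone), with Ccnb2 at -1.68 (SE 0.21) and Mki67 at -1.08 (SE 0.27, adjusted p = 0.0381). All 6 Reg genes fell (6 adjusted over the list alone; Reg2 -5.86, Reg3a -5.81, Reg3b -3.68). Acinar-low spots could still hold enzyme transcripts at under 10% of UMIs. Whole sections held 6.92% of them in vehicle and 0.012% in resistant groups. Leftover acinar tissue in vehicle spots was therefore not set apart from the falls of Reg genes. Kras rose from 670 CPM (SD 143) to 1480 (SD 412), a log2 fold change of 1.14 (SE 0.28, edgeR adjusted p = 0.0317). That call held without resistant section 1 and was lost without any other: 1.30, 1.16 and 0.99 without vehicle sections 1, 2 and 3, and 1.10 and 0.96 without resistant sections 2 and 3 (edgeR adjusted p between 0.0612 and 0.125). It was also lost in the 25% of spots richest in ductal genes, at a smaller 0.68 (edgeR adjusted p = 0.07), with RLE size factors (edgeR adjusted p = 0.0617) and with the Y-linked covariate (edgeR adjusted p = 0.134). With all deposited spots (edgeR adjusted p = 0.602) and at the 20% acinar limit (edgeR adjusted p = 0.597), which let sensitive section 1 into the fit, it was lost too. The calls of Dusp6 and Mki67 were lost under these 2 limits and with that covariate (edgeR adjusted p between 0.112 and 0.613). Cdk8 did not pass (-0.19, SE 0.36, edgeR adjusted p = 0.884).

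Adipocyte genes rose in 6 of 9 members in these resistant spots (8 adjusted over the list alone; Adipoq, which encodes adiponectin, 3.65, and Plin4 2.08). Macrophage genes rose in 4 of 14 with 1 lower (9 and 1 adjusted over the list alone; Trem2 1.15 and Ms4a7 1.03, against Spp1, the osteopontin gene, at -1.46). Endothelial genes rose in 1 of 12 (7 rose and 1 fell adjusted over the list alone; Tek 1.34). The antigen-presentation gene H2-Ab1 fell by 1.25 (SE 0.30) as the single called member of 7 MHC class II genes, and stood at -0.80 without vehicle section 3 (edgeR adjusted p = 0.106). The neutrophil chemokine gene Cxcl5 rose by 1.15 (SE 0.28) as the single called member of 13 myeloid chemokine genes. Other wide changes were rises in Cck (5.74, SE 0.26), the acute-phase gene Hp (4.92, SE 0.89), Serpina3m (4.12, SE 0.71; 2.72 without resistant section 1) and Kcnj12 (3.91, SE 0.42). Wfdc1 (3.81, SE 0.48), the protease inhibitor gene Pzp (3.70, SE 0.62), Krt14 (3.20, SE 0.34), the matrix gene Thbs2 (1.90, SE 0.25) and Dclk1 (1.30, SE 0.17) rose as well. Falls came in Egr1 (-8.30, SE 0.84), the trypsinogen-like gene 2210010C04Rik (-7.72, SE 1.48), Nfatc1 (-5.49, SE 0.30) and the trypsin inhibitor gene Spink1 (-4.84, SE 0.72), and edgeR adjusted p of these 13 rises and falls lay between 1.84e-07 and 0.0109. For 2210010C04Rik and Spink1, as for the Reg genes, leftover acinar tissue in vehicle spots was not set apart.

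By edgeR 599 of 19213 genes rose and 379 fell in these spots, and 19.3% of tested genes did not overlap, where chance gives 10%. The count was 272 without vehicle section 1, 418 without vehicle section 3, 1608 without resistant section 1, 1494 by DESeq2, 108 with the Y-linked covariate, and 27 and 28 under 2 spot limits that let sensitive section 1 into the fit. With a replicate block it was 2018, and 16 lists were called. Of 33 called genes followed, 20 stayed called with any 1 section left out, Dusp6, Adm, Cck and Egr1 among them, whereas Mki67 lost its call without vehicle section 1 (-1.08) or 3 (-0.96) or resistant section 2 (-0.84) or 3 (-1.02), at edgeR adjusted p between 0.0841 and 0.121. Camera called 9 of 35 lists, 4 higher (adipocyte, macrophage, endothelium, myeloid chemokines) and 5 lower (hypoxia, ERK output, cell cycle, Reg family, MHC class II), none with an estimated correlation (lowest adjusted p = 0.588 with an estimated correlation).

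**Figure D3:**
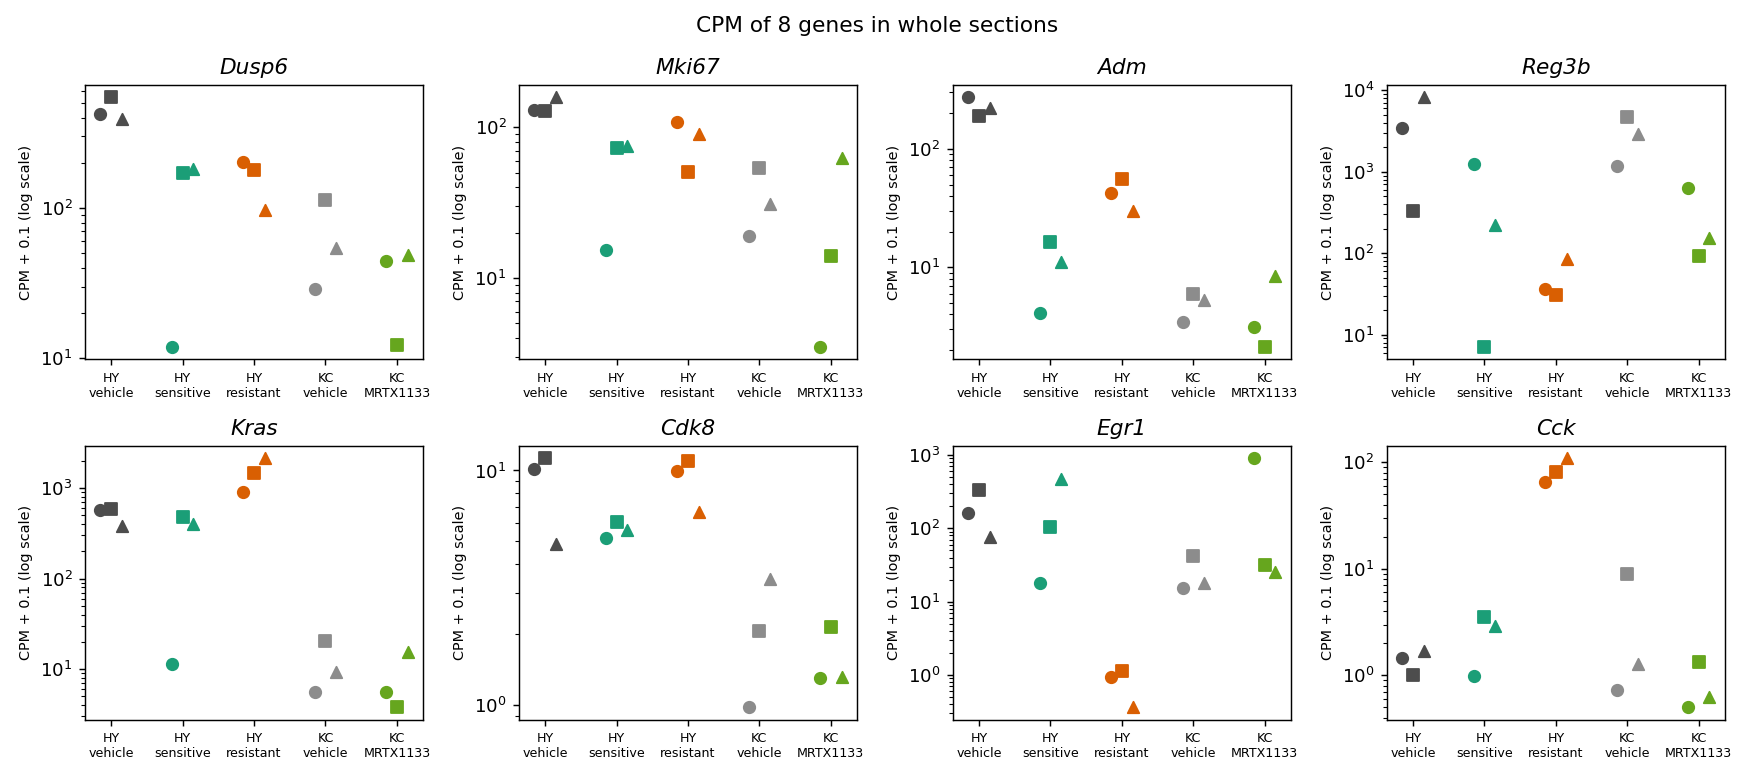
CPM (0.1 added, log axis) of 8 genes in each of the 15 whole sections by group, taken over the section's total before TMM scaling, with marker shape for replicate number. Egr1 lies at or under 1.05 CPM in the 3 resistant sections and at 15.5 CPM or more in the other 12.

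Against sensitive sections, resistant sections had higher gastric-type and ductal genes and lower T cell, dendritic cell and interferon response lists in acinar-low spots. No list call held with an estimated correlation (lowest adjusted p = 0.812 with an estimated correlation). A different share of tumour cells in the spots was not set apart from these rises and falls. Gastric-type genes rose in 9 of 14 members (12 adjusted over the list alone), with Tff1 from 45.2 CPM (SD 1.57) to 742 (SD 428; log2 fold change 4.04, SE 0.69, adjusted p = 0.00372) and Gkn3 at 3.21 (SE 0.60). Ductal genes rose in 7 of 12 (9 adjusted over the list alone; Cldn4 2.94, Krt19 1.28). Hypoxia genes rose in 5 of 12 (7 adjusted over the list alone; Adm 1.95, Pgk1 1.72), and ERK output genes in 6 of 17 with 1 lower (7 and 1 adjusted over the list alone; Dusp5 2.70, Fosl1 1.84). The lower ERK output gene was Egr1. Kras rose by a log2 of 1.95 (SE 0.33, adjusted p = 0.00348), a call lost without sensitive section 2 (1.89, adjusted p = 0.0753) or 3 (2.01, adjusted p = 0.0521), fits that leave 1 sensitive section, whereas Dusp6 (0.10, SE 0.35, adjusted p = 0.843), Mki67 (0.40, SE 0.30, adjusted p = 0.356) and Cdk8 (1.02, SE 0.42, adjusted p = 0.103) did not pass. T cell genes fell in 3 of 14 (11 adjusted over the list alone; Cd5 -2.27, Cd3d -1.71). Dendritic cell genes fell in 5 of 12 (9 adjusted over the list alone; Cd209a -2.07) and interferon response genes in 6 of 14 with 1 higher (8 and 1 adjusted over the list alone; Cxcl10 -1.94, Stat1 -1.23). MHC class II genes fell in 4 of 7 (4 adjusted over the list alone; the transactivator gene Ciita -1.76, H2-Eb1 -1.45) and fibroblast genes in 3 of 14 (3 adjusted over the list alone; Dcn -1.33). Among cytotoxic lymphocyte genes 1 of 13 fell, the T-bet gene Tbx21 (-1.204, SE 0.38).

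Wide rises in that comparison came in Il5ra (5.22, SE 1.09), Cck (5.00, SE 0.30) and Serpina3m (4.99, SE 0.90). Dynap (4.54, SE 0.49), the neuropeptide gene Npy (4.52, SE 1.11) and Tff3 (4.38, SE 1.29) rose as well. Their order rests on single sections, since without resistant section 1 Il5ra stood at 3.02 and Npy at 1.87. Wide falls came in Egr1 (-8.51, SE 0.87), Nfatc1 (-5.52, SE 0.31), Cyp2d22 (-5.10, SE 0.27), Stk38 (-4.05, SE 0.28), Angptl7 (-4.02, SE 0.47) and Gdf10 (-3.96, SE 0.61), and edgeR adjusted p of all 12 lay between 1.14e-06 and 0.0329. By edgeR 3495 of 19213 genes passed, 2359 higher and 1136 lower, and 55.5% of tested genes did not overlap, where chance gives 20% for 2 against 3 sections. The count was 152 without sensitive section 2, 352 without sensitive section 3, 1815 without resistant section 2, 5605 without resistant section 3, and 1215 and 1545 under the 2 spot limits that let sensitive section 1 in. Without sensitive section 2 or 3 the arm is 1 section, which is assumed to vary like the other groups. Of 30 called genes followed, 26 stayed called in the fits that kept 2 or more sections per group. With the lone sections counted too, 10 did: Angptl7, Cck, Cldn4, Cyp2d22, Dusp5, Dynap, Egr1, Gdf10, Nfatc1 and Stk38. Camera called 11 of 35 lists, 4 higher and 7 lower, none with an estimated correlation (lowest adjusted p = 0.812 with an estimated correlation).

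Over whole sections the same comparison was led by exocrine genes. Acinar enzymes fell in 22 of 25 members (25 adjusted over the list alone), as did the acinar transcription factor gene Rbpjl (-11.00, SE 2.78). The acinar protein-folding genes Pdia2 (-9.80, SE 2.34) and Erp27 (-8.34, SE 2.05), the zinc transporter gene Slc39a5 (-7.46, SE 1.79), Cabp2 (-7.42, SE 1.75) and Egr1 (-7.89, SE 1.13) fell too, with edgeR adjusted p between 0.0118 and 0.0351 when Rbpjl is counted in. Rbpjl stood at 2036 CPM in sensitive section 1 against 1.66 and 136 in the other sensitive sections. Without section 1, Pdia2 stood at -6.40, Erp27 at -5.24, Slc39a5 at -4.32 and Cabp2 at -4.43. Il5ra (5.48, SE 1.04), Cck (5.13, SE 0.32), Npy (4.99, SE 1.15), Tff3 (4.84, SE 1.33), Tff1 (4.63, SE 1.00) and Serpina3m (4.50, SE 0.87) rose, and Cldn4 (3.27) and Dusp5 (3.26) with them, while Cd3d (-1.76) and Zbtb46 (-1.64) fell. Without resistant section 1, Il5ra stood at 3.23 and Npy at 2.29 (edgeR adjusted p = 0.0748). Kras (2.55, SE 0.80, edgeR adjusted p = 0.0554), Mki67 (0.69, SE 0.36, edgeR adjusted p = 0.163), Dusp6 (0.64, SE 0.59, edgeR adjusted p = 0.396) and Cdk8 (0.48, SE 0.45, edgeR adjusted p = 0.402) did not pass. By edgeR 2587 of 19233 genes passed, 1675 higher and 912 lower, with 48.9% of genes not overlapping against 10% by chance. The count was 39 without resistant section 2, 78 without resistant section 1, 1584 and 1397 without sensitive sections 2 and 3, 5669 by DESeq2, 1381 with the Y-linked covariate and 39 in a fit of the 6 sections alone. Of 18 called genes followed, Cck and Cldn4 alone stayed called with any 1 section left out. Camera called 13 of 36 lists, 7 higher and 6 lower, none with an estimated correlation (lowest adjusted p = 0.883 with an estimated correlation).

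In KC pancreas no single gene passed the test between MRTX1133 and vehicle, while lists of gastric-type, ductal, fibroblast and Reg genes were lower on MRTX1133 by camera at the preset correlation. None held with an estimated correlation (lowest adjusted p = 0.455 with an estimated correlation) or by fry (lowest adjusted p = 0.385). Gastric-type genes had a median log2 fold change of -5.33 over 13 members (none called over all genes, 8 adjusted over the list alone). The gastric gene Gkn3 stood at 74.5 CPM (SD 72.1) on vehicle and 0.855 (SD 0.623) on MRTX1133 (-6.89, SE 1.04, edgeR adjusted p = 0.508), and the mucin gene Muc6 at 101 (SD 97.4) and 2.94 (SD 2.47). Cldn4 had the lowest adjusted p of all genes (-4.22, SE 0.47, edgeR adjusted p = 0.155), in a ductal list with a median of -1.82. Fibroblast genes had a median of -1.45 (6 of 14 lower adjusted over the list alone), with the collagen gene Col1a1 at 887 CPM (SD 530) and 66.02 (SD 36.7). Reg genes had a median of -2.52 (5 of 6 lower adjusted over the list alone), with Reg3a at -3.52 (SE 1.04) and Reg3g at -3.71 (SE 1.01). Spp1 stood at 414 CPM (SD 278) and 14.98 (SD 12.5), the protease gene Mmp2 at 99.8 (SD 49.2) and 14.4 (SD 6.43) and the ERK-driven gene Etv4 at 12.4 (SD 5.61) and 3.41 (SD 2.06). Adipocyte genes had a median of 3.75 (8 of 8 higher adjusted over the list alone; Cidec 3.73, SE 0.82, and Pck1 3.78, SE 0.85).

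Dusp6 (-0.46, SE 0.51), Mki67 (-0.25, SE 0.69), Kras (-0.18, SE 0.46) and Cdk8 (-0.25, SE 0.64) each had an edgeR adjusted p = 1 in whole KC sections. EdgeR called 0 of 14090 genes there, with 633 at an unadjusted p under 0.05, and DESeq2 called 83. Of tested genes 7.88% did not overlap, where chance gives 10%. Camera called 17 of 33 lists, 3 higher (adipocyte, acinar enzymes, interferon response) and 14 lower, none with an estimated correlation (lowest adjusted p = 0.455 with an estimated correlation), and fry called 0 (lowest adjusted p = 0.385). The T cell list was called lower although its median was 0.54.

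In acinar-low KC spots, where MRTX1133 sections 1 and 3 stood against 3 vehicle sections, camera at the preset correlation called the same epithelial lists lower and the islet list with them. None held with an estimated correlation (lowest adjusted p = 0.367 with an estimated correlation). Gkn3 stood at 223 CPM (SD 216) on vehicle and 1.54 (SD 1.74) on MRTX1133, Cldn4 at 166 (SD 96.4) and 6.33 (SD 6.75), and Agr2 at 68.6 (SD 75.3) and 1.39 (SD 1.96). With 1 section left out, the log2 fold change of Agr2 ran from -10.97 to -4.74. The chloride channel gene Cftr, at 12.0 CPM (SD 4.23) on vehicle, was listed at 0 on MRTX1133. The islet hormone genes Sst and Ppy stood at 328 (SD 258) and 415 CPM (SD 469) on vehicle and 23.7 (SD 13.6) and 6.49 (SD 6.53) on MRTX1133. The adipocyte gene Plin1 stood at 32.9 (SD 8.46) and 826 (SD 1014) and Cidec at 17.0 (SD 15.5) and 454 (SD 413), none of them called. The log2 fold change of Plin1 ran from 1.79 to 5.50 with 1 section left out. Dusp6 (0.26, SE 0.45), Mki67 (-0.22, SE 0.70) and Kras (0.08, SE 0.45) had an edgeR adjusted p = 1, and Cdk8 had too few counts to be tested. EdgeR called 0 of 12056 genes, with 675 at an unadjusted p under 0.05, DESeq2 called 144, and edgeR called 99 without MRTX1133 section 3, all higher. That fit sets section 1 alone against vehicle and assumes that it varies like them. Of tested genes 17.2% did not overlap, where chance gives 20%. Camera called 13 of 31 lists, 6 higher and 7 lower, none with an estimated correlation (lowest adjusted p = 0.367 with an estimated correlation).

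The test of a difference between the effects of MRTX1133 in the 2 models set 1 week in HY mice against 18 weeks in KC mice. It passed for few genes. By the bound set chance could not be excluded for their count, which some other groupings of the KC sections matched or passed. For Adm the effects differed by a log2 of -4.92 (SE 0.66, edgeR adjusted p = 0.0223), from an effect of -4.82 in HY and 0.10 in KC in the models' own fits, whose difference need not equal that of the joint fit. Before TMM scaling, Adm lay between 2.0 and 8.4 CPM in KC sections, against at least 189.9 in HY vehicle sections. At that low level a fall as large as in HY could hardly show in KC. Cited1 (-5.82, SE 0.92), Acan (-5.47, SE 1.06), the magnesium transporter gene Nipal1 (-4.49, SE 0.67), Fam71f2 (-4.39, SE 0.77) and the brain protease gene Prss12 (-3.70, SE 0.56) also had the more negative effect in HY. The more positive effect in HY fell on Sertad4 (4.76, SE 0.80), the angiopoietin gene Angpt4 (4.75, SE 0.91) and the fibroblast gene Pi16 (4.66, SE 0.69, from 2.29 in HY and -2.21 in KC). The ghrelin gene Ghrl (4.58, SE 0.79), the elastic fibre gene Mfap4 (4.55, SE 0.87) and Asz1 (4.09, SE 0.68) had it too, with edgeR adjusted p between 0.0223 and 0.0487 for all 12. Dusp6 (-1.86, SE 0.88, edgeR adjusted p = 0.277), Mki67 (-1.58, SE 0.91, edgeR adjusted p = 0.363), Kras (-1.18, SE 1.02, edgeR adjusted p = 0.536) and Cdk8 (-0.38, SE 0.73, edgeR adjusted p = 0.792) did not pass. By edgeR 41 of 19204 genes passed, 22 with the more positive and 19 with the more negative effect in HY, and 3461 had an unadjusted p under 0.05. The count ran from 0 to 439 with 1 section left out and was 0 with the Y-linked covariate. None of the 12 genes stayed called with each section left out in turn. Adm lost its call without HY vehicle section 1 or KC vehicle section 1 or 2. Regrouping the KC sections while the HY groups stayed gave up to 627 genes.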

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

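The tests of exchanged labels, of the share of tumour cells and of immediate-early genes were chosen after the values they measure had been seen. By edgeR, 41 genes passed the test of a difference between the effects of MRTX1133 in HY and KC mice. Among them were Acan (-5.47), Adm (-4.92), Cited1 (-5.82), Fam71f2 (-4.39), Nipal1 (-4.49) and Prss12 (-3.70), with the more negative effect in HY. Those with the more positive effect in HY were Angpt4 (4.75), Asz1 (4.09), Ghrl (4.58), Mfap4 (4.55), Pi16 (4.66) and Sertad4 (4.76). Of 100 drawn splits within the models, 5 gave as many genes, the real one included, so by the bound set chance could not be excluded. All 5 kept the real split of the HY sections: with the KC sections regrouped, 4 of 7 other draws gave 55, 128, 160 and 627 genes, and no draw with another HY split gave more than 1. This points to a structure of the samples that follows the HY groups. Draws that keep these groups carry the difference between them, so they do not measure chance in it. The 41 genes cannot be laid to the real groups of KC sections.

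Egr1, Nfatc1, Cyp2d22 and BC003965, excluding acinar enzymes, lay in all 3 resistant sections at under 0.5 of the lowest of the other 12 sections in CPM before TMM scaling, and were chosen after their values were seen. Only genes over 2 CPM in each of those 12 sections were considered. For a loss in tumour cells alone, the median ratio of resistant to vehicle CPM was compared between kinds of spots, before TMM scaling. It was 1.42 times as high in spots richest in stromal and immune genes as in those richest in ductal genes. A loss in tumour cells alone needed 5 times or more. The genes thus lay below vehicle in both kinds of spots. This cannot decide which cells lost them, because low values over whole sections chose the genes. Stroma-rich spots can also hold tumour transcripts. A fall of immediate-early genes as a group, as large as that of Egr1 (-8.28), was argued against. The 9 others had a median log2 fold change of -0.59 and none lay under -2.42. A smaller fall of some of them stays open, with Fosb at -2.42, Fos at -2.39, Atf3 at -2.27 and Junb at -1.28 (none called) and Jun at 0.47. A lower yield of these probes in the resistant libraries stays open and cannot be told apart from a loss in the tissue, because libraries and groups coincide. The highest ratio of any of the 4 genes in either kind of spot was 0.39, of BC003965 in ductal-rich spots. That ratio lay over the bound set for a lower yield and under the bound set against it. The ratios of Egr1, Nfatc1 and Cyp2d22 were at most 0.0813 in both kinds of spots, under the bound set for a lower yield. In the 10% of spots richest in Fos, Egr1 stood at 0.718 CPM in resistant and 475 CPM in vehicle sections. The longer treatment and resistance itself were not tested as biological explanations.

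HY sensitive section 1 held the 60 genes of the tumour line, those at least 10 times higher in all vehicle and resistant HY sections than in any KC section, at a median of 1.98 CPM before TMM scaling, against at least 36.8 in the other 8 HY sections. A label exchanged with a KC section was tested over such genes chosen without the KC section in question. KC sections other than vehicle section 2, 5 in all, reached at most 0.0373 of the lowest of those 8. That lies under the bound set and argues against an exchange with them. KC vehicle section 2 reached 0.241, between the bounds, so an exchange with it stays open. Its set grew to 251 genes, against 60 to 69 for the others, and so took in genes that this section itself holds. Kras and Cdkn2a ran against an exchange, at most 20.3 and 32.0 CPM in any KC section against at least 381 and 490 in those 8. They are only 2 genes, Cdkn2a was chosen after its values were seen, and a single wrong label needs no partner. A section with little tumour beside exocrine pancreas stays open, since its acinar-low spots held these genes at 5.6 times the level in its other spots (95% counting interval 5.06 to 6.18), between the bounds of 10 and 3 set for and against it. Regression of the tumour under MRTX1133 was not tested.

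The lower ERK output, hypoxia and cell cycle lists in acinar-low spots of sensitive sections had medians of -1.34, -2.34 and -1.27. A smaller share of tumour cells in those spots stays open. The 60 genes of the tumour line had a median of -1.56 (quartiles -2.68 and -0.83). They were chosen for high levels in vehicle and resistant sections alone. That choice favours a fall in sensitive sections, so it cannot decide. In whole sections before TMM scaling, sensitive sections 2 and 3 held the 60 genes at medians of 39.1 and 36.8 CPM, against at least 72.4 in vehicle sections. Their Kras, Cdkn2a and Epcam lay within the range of the vehicle sections. Fewer epithelial cells among the spots stay open too: in the 25% of spots richest in ductal genes the lists stood at -1.06, -2.71 and -0.75, the least negative of which lies between the bounds set. Inhibition of KRAS itself, the biological explanation that the groups give, was not tested apart from these, and genes of the tumour line can answer to it as well.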

How the results depend on the processing

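Of 230 gene values named, 217 kept their direction under every alternative run, and of the 182 past the threshold, 55 stayed past it under all of them. Where a count moved, the cause was not tested unless fewer sections or genes show it. Counts below are of genes past the threshold unless lists are named. DESeq2 gave 6193, 301 and 5669 genes in whole HY sections (sensitive against vehicle, resistant against vehicle, resistant against sensitive), 83 in whole KC sections, 1494 for resistant against vehicle in acinar-low spots and 144 in KC acinar-low spots. Fits of only the 6 sections compared gave 1688, 409 and 39 in whole HY sections, and KC in a fit of all 15 sections gave 4. RLE size factors gave 173 for the difference between models and 15 lists for resistant against vehicle in acinar-low spots. They and DESeq2 moved the median of all genes by -0.131 in acinar-low spots of sensitive against vehicle sections. Thinned sums gave 151 for the difference between models. Including all deposited spots gave 28 and 1215, and an acinar limit of 20% gave 27 and 1545, for resistant against vehicle and against sensitive in acinar-low spots, with sensitive section 1 entering the fit. The 25% of spots richest in ductal genes gave 2927 for resistant against vehicle. The same rule gave 107 in KC. There it kept every acinar-low spot of MRTX1133 sections 1 and 3 (466 and 669 spots), because their cut lay at 0%. In KC it thus set ductal-rich spots of vehicle sections against all acinar-low spots of MRTX1133 sections. An estimated correlation gave 0 lists in all 8 list tests. Fry gave 1, 0, 0 and 0 lists in whole sections (the 3 HY comparisons, then KC) and 7, 0, 0 and 0 in acinar-low spots. The remaining alternatives (no low-count filter, 500 UMIs per spot, a 5% acinar limit, acinar enzymes left out) kept every count within 1.5 times.

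The presence of Y-linked transcripts as a covariate, chosen after seeing the data, gave 12, 5 and 1381 genes in whole HY sections, 0 for the difference between models, and 1701 and 108 for sensitive and resistant against vehicle in acinar-low spots. In HY the 2 sections without them were both vehicle, so it overlaps with the groups. It turned Cdk8 to 0.10 and 0.58 in whole sensitive and resistant sections against vehicle and to 0.75 in resistant acinar-low spots, and Kras to -0.076 in KC acinar-low spots.

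Same-numbered sections deviated together (correlation over 0.1) in all 3 pairs of HY vehicle and resistant sections, in whole sections and in acinar-low spots, where each correlated best with its own number. In whole sections 1 of 3 pairs did so for sensitive and vehicle, 1 of 3 for resistant and sensitive and 0 of 3 in KC. A replicate block gave 2437, 9 and 676 in whole HY sections, 2 in KC, 3 for the difference between models, 2018 genes and 16 lists for resistant against vehicle in acinar-low spots, and 156 in KC acinar-low spots, and turned Dusp6 to -0.14 for resistant against sensitive in acinar-low spots.

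With 1 section left out, counts of genes ran from 527 to 5177 (sensitive against vehicle), 5 to 15 (resistant against vehicle), 39 to 3485 (resistant against sensitive) and 0 to 0 (KC; by edgeR, with 633 at an unadjusted p under 0.05 and 83 by DESeq2 when all were kept) in whole sections, and from 1933 to 6226, 272 to 1608, 152 to 5605 and 0 to 99 in acinar-low spots. There, a fit without HY sensitive section 2 or 3 or KC MRTX1133 section 1 or 3 leaves a lone section, assumed to vary like the other groups. Lists ran from 8 to 16, 9 to 16, 11 to 17 and 13 to 20, and from 14 to 19, 9 to 14, 10 to 16 and 11 to 18. Besides the sections named in the report, whole resistant against vehicle fell to 5, 15 and 11 without vehicle sections 1, 2 and 3 and to 10, 8 and 6 without resistant sections 1, 2 and 3. Lists rose to 16 in whole sensitive against vehicle sections without sensitive section 1 and to 14 for resistant against vehicle in acinar-low spots without resistant section 2. The difference between models ran from 0 to 439: 0, 3 and 17 without HY vehicle sections 1, 2 and 3, 302, 9 and 2 without HY sensitive sections 1, 2 and 3, 0 and 0 without KC vehicle sections 1 and 2, and 164 and 439 without KC MRTX1133 sections 1 and 3.

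Genes outside the threshold changed sign as follows. Cdk8 ran with 1 section left out from -0.49 to 0.042 in whole resistant against vehicle sections, from -0.50 to 0.079 in acinar-low spots and from -0.52 to 0.33 in KC, and was 0.35 for the difference between models in thinned sums. Dusp6 ran from -0.16 to 0.43 for resistant against sensitive and from -0.38 to 0.68 for KC in acinar-low spots. Kras ran in KC from -0.70 to 0.14 in whole sections and from -0.49 to 0.37 in acinar-low spots. Mki67 ran from -2.09 to 0.19 for the difference between models and in KC from -1.61 to 0.26 in whole sections and -2.19 to 0.58 in acinar-low spots. In the 25% of spots richest in ductal genes Dusp6 was -0.094 and Mki67 -0.37 for resistant against sensitive. In KC, where this rule kept all acinar-low spots of the MRTX1133 sections, Mki67 was 1.05, Dusp6 -0.043 and Kras -0.10. In KC acinar-low spots Mki67 was 0.011 in thinned sums, and under the 20% acinar limit Mki67 was 0.15 and Dusp6 -0.014.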

Other observations

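In whole HY sections, islet genes were lower in resistant than in vehicle sections by camera at the preset correlation (median log2 fold change -1.15, adjusted p = 0.0458; adjusted p = 0.881 with an estimated correlation), beside acinar enzymes at a median of -9.07. Smooth and skeletal muscle genes were higher (median 1.40, adjusted p = 0.0158; adjusted p = 0.849 with an estimated correlation). The muscle list had a median of 1.38 in sensitive against vehicle sections (adjusted p = 0.0971) and was not called between resistant and sensitive sections (adjusted p = 0.603). In KC acinar-low spots, genes of checkpoints and regulatory T cells (median 0.67, adjusted p = 0.00226) and of MHC class I (median 0.41, adjusted p = 0.0159) were higher on MRTX1133, neither with an estimated correlation (adjusted p = 0.367 and adjusted p = 0.731 with an estimated correlation). The Mediator kinase module, which holds Cdk8, was called in none of the 8 tests by camera, with adjusted p = 0.357 in whole and 0.652 in acinar-low sensitive against vehicle sections.

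Groups of 3 against 3 sections allow 10 splits, too few for a share under 0.05. For genes in whole sections, 1 of the 10 splits, the real one, gave as many as the real 4061 (highest other 0) for sensitive against vehicle, 1 gave as many as 28 (highest other 3) for resistant against vehicle, and 1 as many as 2587 (highest other 0) for resistant against sensitive. The 4 splits of vehicle and resistant sections that part every same-numbered pair include the real one, and the other 3 gave 0 genes by edgeR in whole sections and in acinar-low spots. At the preset correlation camera called 15, 20 and 17 lists in these 3 in whole sections, against 12 in the real split. In acinar-low spots it called 14, 20 and 18, against 9. In KC all 10 splits gave as many as the real 0 by edgeR (highest other 0; 633 at an unadjusted p under 0.05 and 83 by DESeq2 in the real split). For resistant against vehicle in acinar-low spots, 1 split, the real one, gave as many as the 599 rises and 379 falls together (highest other 20).

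For lists by camera at the preset correlation, 9 of the 10 splits gave as many as the real 10 for sensitive against vehicle (highest other 19). As many as the real 12 for resistant against vehicle came from 7 splits (highest other 20), and as many as the real 13 for resistant against sensitive from 8 splits (highest other 19). In KC 1 split, the real one, gave 17 (highest other 16). In acinar-low spots 8 splits gave as many as the real 9 for resistant against vehicle (highest other 20). Splits were not made for the other comparisons in acinar-low spots.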
